A study of Homo sapiens with 3 samples.

How the data were processed

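Guide RNA abundance was measured in genomic DNA of AF22 neural stem and progenitor cells. Per the labels' protocols, cells were transduced with the Brunello library at an MOI (viral particles per cell) of 0.5 and selected for 2 days in 0.5 µg/mL puromycin. Part of the cells was then replated for 10 days of differentiation, and the remainder made up the day-0 sample. The guide cassette was amplified over 28 PCR cycles, and no molecular identifiers are named in those protocols. Each of the 3 groups (day 0, sorted on CD133, sorted on CD24) has 1 library, so no spread between replicates can be had.

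The authors deposited raw read counts per guide for 77441 guides, per the file headers, with a list of the 20-base guide sequences (another kind of value, text). The authors also deposited a score per gene for each pair of groups, an enrichment value whose model and scale are not given in the sources used here. MAGeCK 0.5.9.4 is named in the submitters' processing notes, without a step. No genome was used. Gene names are those of the files; of 19114 names, 17852 are current symbols in the RefSeq table of GRCh38.p14, 1135 matched 1 gene through an older symbol and 127 had no match.

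Counts were scaled by library totals to CPM. For each guide the difference of log2(CPM + 1) was taken between libraries and centred on the median of the non-targeting guides. Guides with at least 2 CPM at day 0 were kept, 54860 in all, 911 of them non-targeting and 1065 against olfactory receptor genes. A gene's value is the median over its guides, for genes with at least 3 (12546 genes, 5253 with 4). Such differences understate the change of low guides. A gene was past the size rule when its value was at least 1 in size and at least 3 guides lay beyond the 5th or 95th percentile of non-targeting guides. This is a rule of size and not a test between conditions. It was set against 10000 sets of non-targeting guides, 10000 sets of olfactory receptor guides and 20 simulated sets of unchanged libraries, in which guides drew Poisson numbers of units worth the reads at the tallest peak of reads per guide. Each guide's expected share was the mean of its shares in the 3 libraries. Sampling noise and any real change in them are thus carried into the simulations. Smaller peaks were taken as the highest value within 4 bins of 10 reads on either side, after smoothing over 3 bins.

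Gene lists were compared by the median of their gene values and its percentile among 10000 random lists of the same size, matched on deciles of day-0 abundance. A list outside percentiles 2.5 to 97.5 was called lower or higher, as a description of these libraries. There were 43 lists fixed before the data were examined, plus a core list joining 7 of them and the 374 olfactory receptor genes. Of the fixed lists 2 are not reported here, nor are 3 single genes, and counts of lists leave those out. Of the list members 3 had no match in the library (POU3F3, RNF43 and RYBP).

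Genes are named by a rule. It takes the 10 highest and 10 lowest past the size rule per comparison, PROM1 and CD24 always, up to 3 members past the rule from each list or otherwise 2 with the largest values, the 5 highest and 5 lowest of the authors' deposited table, and genes past the rule in opposite directions. Genes shared by both comparisons were also listed, after their values were seen, and most of the list examples under the rule are left out for length.

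The scripts were tested on simulated data. Of simulated genes lowered to 0.1 of day 0, 23.4% of 158 passed the size rule in the comparison of CD133 with day 0 and 19.0% of 158 in that of CD24 with day 0. At 0.25 the shares were 13.1% and 8.50% of 153, at 4-fold 19.7% and 26.1% of 142, and at 10-fold 85.3% and 87.3% of 150. Of 55185 unchanged simulated genes 0.448% and 0.187% passed. In each of 5 simulations 1 list of 40 genes was lowered to 0.5 of day 0 and scored in both comparisons. All 10 of these scores lay below percentile 2.5, and of 10 unchanged lists 1 did. In these simulations, which rest on that unit, the rule missed most genes lowered to 0.1 or 0.25 of day 0 or raised 4-fold and found most raised 10-fold. Shorter lists were not simulated.

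Alternatives fixed before the data were examined covered the centring (olfactory receptor guides, none, median-of-ratios size factors), the pseudocount (0.2 and 5 CPM), the guide minimum (none, 5 CPM), the mean of guides, leaving out the most extreme guide, a 2.5 to 97.5 percentile range, size thresholds of 0.5 and 2, unmatched random lists, and thinning to the shallowest total. Chosen after seeing the data were a guide range from olfactory receptor guides, summed CPM of all guides, and zeros set to 3 counts without a pseudocount, 20 simulations with a unit of 0.5 of the tallest peak, other minimums for guides unread at day 0, and most of the alternatives for the correlation between both changes from day 0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.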

Results

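A pooled CRISPR knockout screen was sequenced in AF22, an established line of human neural stem and progenitor cells derived from induced pluripotent stem cells. The Brunello lentiviral library, which carries Cas9 and 1 guide RNA per vector, holds 76441 guides against 19114 genes and 1000 non-targeting guides. Guide abundance was counted in 3 libraries of genomic DNA, 1 per group. The first came from cells before differentiation (day 0). The others came from cells cultured for 10 days without the growth factors FGF and EGF and sorted on CD133, a surface protein of undifferentiated neural progenitors encoded by PROM1, or on CD24, a surface protein of neurons in this system. The screen asked which knockouts change proliferation of these cells. With 1 library per group, no difference below has a replicate check, no p-value is given across genes, and guides or genes are not counted as replicates.

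The knockouts of the sort antigens were examined first, because they check the sort labels. PROM1 guides, which remove CD133, held 2855 reads at day 0, 2560 reads in the CD133 library and 0 reads in the CD24 library. In the CD133 library, 2202 of these reads came from guide CTGTGAACCTTACACGAGCA, which had 1 read at day 0. CD24 guides held 2560 reads at day 0, 345 in the CD133 library and 1531 in the CD24 library. Guide GAGTACTTCCAACTCTGGGT went from 1259 reads at day 0 to 1 read in the CD133 library and held 816 in the CD24 library. The other CD24 guides disagreed, with 1, 343 and 0 reads in the CD133 library and 388, 327 and 0 in the CD24 library. Loss of an antigen removes a cell from the sort on that antigen, so between the sorted libraries the summed reads of both genes ran against the labels, those of PROM1 mostly through that guide. The other PROM1 guides fell from day 0 to the CD133 library, as the label predicts (1427 to 0, 1168 to 358 and 259 to 0 reads). They also had 0 reads in the CD24 library, so the PROM1 median was -3.01 in CD133 over day 0, -5.02 in CD24 over day 0 and 0 between the sorted libraries. The check is thus mixed. The libraries are called the library labelled CD133 and the library labelled CD24 throughout, and every direction between them or from day 0 rests on labels that this check did not settle.

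**Figure D1:**
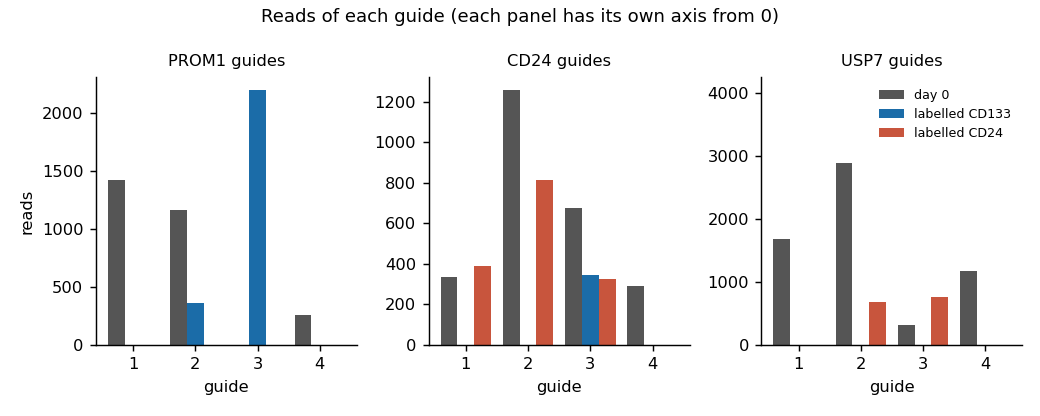
Reads (vertical axis, linear from 0, a separate scale per panel) of each of the 4 guides against PROM1, CD24 and USP7 in the day-0 library (grey), the library labelled CD133 (blue) and the library labelled CD24 (red). PROM1 guides have 0 reads in the library labelled CD24, and PROM1 guide 3 holds 2202 of the 2560 reads in the library labelled CD133.

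The day-0 library held 46283055 reads, the library labelled CD133 35547159 and the library labelled CD24 35482665. The median guide had 436, 297 and 341 reads. Guides without a read made up 21.2% of the library at day 0 (95% exact binomial interval 20.9 to 21.5%), 36.6% in the library labelled CD133 (36.3 to 37.0%) and 36.6% in the library labelled CD24 (36.3 to 37.0%). Among non-targeting guides the shares were 4.9%, 8.7% and 7.9%. The median non-targeting guide had 1077 reads at day 0, against 431 for targeting guides. A count of 0 allows up to 3 reads, or 0.0648, 0.0844 and 0.0845 CPM. The intervals treat guides as independent draws, and the floors cover the counting of reads only. Neither covers the drawing of templates or a spread between replicates. Reads per guide fell into separate peaks, the tallest at 295, 315 and 355 reads and the next above it at 485, 525 and 735. Smaller peaks lay below it, at 75 and 155 reads at day 0, 85 and 155 in the library labelled CD133 and 185 in the library labelled CD24. Total reads divided by the reads at the tallest peak gave 2.03, 1.46 and 1.29 per guide.

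**Figure D2:**
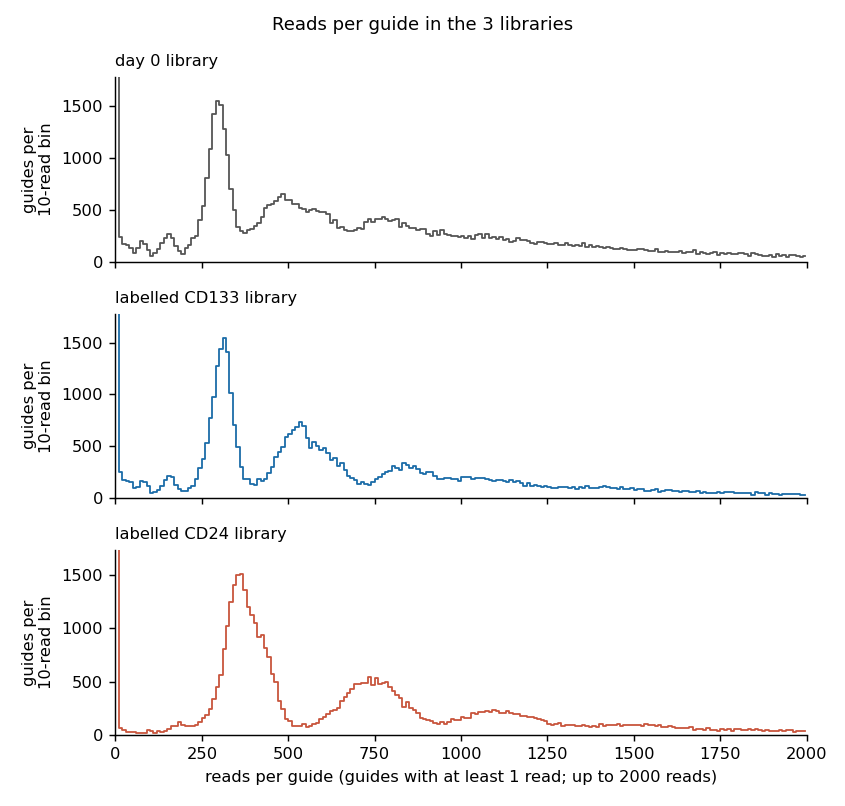
Number of guides (vertical axis, per 10-read bin) against reads per guide (horizontal axis, linear) for guides with at least 1 read; the lowest bin runs off the axis. The tallest peak lies at 295 reads at day 0, 315 in the library labelled CD133 and 355 in the library labelled CD24, with smaller peaks below it.

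Guides against genes of core cell functions lost ground in the library labelled CD133 relative to day 0. Their mean abundance fell from 11.5 to 7.33 CPM, a summed ratio of 0.637, while guides against olfactory receptor genes, which are silent in neural cells, went from 13.5 to 14.4 CPM. Of 169 measured core genes, 152 had a median guide change below the non-targeting guides, as had 79.4% of all genes, and the core median was -2.46 on the log2 scale. It lay below all 10000 random lists matched on day-0 abundance, whose central 95% ran from -1.39 to -0.73. Without a pseudocount and with counts under 3 set to 3, chosen after seeing the data, the core median was -4.18. Without a guide filter it was -1.38, with a pseudocount of 5 CPM -1.41 and with summed CPM, chosen after seeing the data, -0.65. Under each of these it stayed below every random list. The median of all 12546 genes tested was -1.0, so values are read against the random lists and not against 0. With the median of the olfactory receptor guides as the centre that median was -0.29, with no centring -0.71, with median-of-ratios size factors -0.91 and without a guide filter, over 19107 genes, -0.47.

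Of the 43 lists, 6 lay below the central 95% of random lists in this comparison. Of 43 random lists, 2.15 would be expected outside it, both sides together. Cytosolic ribosomal proteins had a median of -3.16 over 43 measured genes, and RPS20 (median -4.66; 4077 reads at day 0, 0 in the library labelled CD133) was the member past the size rule. DNA replication genes had a median of -2.75 over 28 genes, with POLD3, a subunit of DNA polymerase delta, at -4.52. The spliceosome list lay at -2.57 over 25 genes, with SF3B2 of the U2 particle at -4.69. The mitosis list lay at -2.13 over 25 genes, with the mitotic kinase PLK1 at -4.26 (2718 reads to 2). Drivers of the G1/S transition had a median of -2.76 over 10 measured members, none past the rule, with CDK4 at -4.49 and E2F1 at -4.30. That call was lost without a guide filter (percentile 34.1) and with summed CPM (7.3). The core list, the union of 7 lists, is the other. Olfactory receptor genes lay above their random lists at -0.73 (percentile 99.4), a call lost without a guide filter (90.8) and with a filter of 5 CPM.

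The size rule was met by 2 genes upward and 66 downward in the library labelled CD133 over day 0. The balance depends on the measure: without a guide filter 18 passed upward and 94 downward, and by summed CPM, chosen after seeing the data, 131 and 149. The upward pair was ACSBG2, an acyl-CoA synthetase (median 2.54; 1542 reads to 6404), and FUT2, a fucosyltransferase (2.07; 1534 to 4120). The lowest medians were those of the prefoldin subunit PFDN2 (-5.69; 4611 reads to 0), BRD1 of histone acetyltransferase complexes (-5.50; 4357 to 1), MKL2, a coactivator of serum response factor now named MRTFB (-5.39; 7236 to 353), BANP (-5.34; 4258 to 0) and STK32B (-5.30; 4426 to 1). They were followed by the deubiquitinase USP7 (-5.26; 6074 to 1), TRPC4AP (-5.18), the minor spliceosome protein SNRNP25 (-5.11; 4643 to 0), DISC1 (-5.10) and CCKAR (-5.10). A guide with 0 reads sits at the pseudocount, so the depth of these medians follows the reads at day 0. For TRPC4AP the 3 measured guides fell while its total was 3362 and 2614 reads, the remainder coming from a guide under the day-0 minimum. In DISC1 and CCKAR a measured guide rose, from 617 to 792 and from 452 to 838 reads.

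Other members past the rule were POLR2I (-4.61) and POLR3E (-4.57) of the RNA polymerases, the complex I assembly factor TIMMDC1 (-4.46), MRPL41 (-4.99) and MRPL53 (-4.42) of the mitochondrial ribosome, BCL2L2 (-4.71) of the survival proteins, and TLN1 (-4.58) and LIMS1 (-4.41) of integrin adhesion. Of the core genes 6 of 169 were past the rule downward and of the olfactory receptor genes 0 of 251. Both counts are limited by the reads at day 0. The 5th percentile of non-targeting guides was -4.13, and a USP7 guide that went from 309 reads to 0 had only -3.23. The median targeting guide had 431 reads at day 0. Sets of olfactory receptor guides led to an expectation of 0.53 genes upward and 31.8 downward, and sets of non-targeting guides to 2.31 and 1.58. Under the same day-0 filter, 20 simulations of unchanged libraries also passed more genes downward than upward. Their mean was 3.8 upward and 27.5 downward, the latter with a range of 8 to 80. The count of 66 lay inside that simulated range, and below the 104 to 202 of simulations with a unit of 0.5 of the tallest peak, chosen after seeing the data. With the guide range taken from olfactory receptor guides, an alternative chosen after seeing the data, 5 genes were past the rule upward and 8 downward.

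The remaining lists lay inside the central 95% of random lists in this comparison. Among core lists these were the proteasome at -1.70 (PSMA5 at -5.19), RNA polymerases at -2.08 and tRNA synthetases at -2.18 (MARS at -3.64). Mitochondrial lists were complex I at -1.83 and the mitochondrial ribosome at -0.86. Growth control lists were G1/S brakes at -0.91, mTORC1 brakes at -1.35, PI3K-mTOR drivers at -0.75, Hippo brakes at 0.02 (percentile 97.3), YAP/TEAD effectors at -1.89, RAS brakes at -2.24 and EGF, FGF and MAPK signalling at -1.51. Signalling lists were Notch at -2.38 (percentile 2.55; HEY1 at -4.00, RBPJ at -3.88), Wnt at -0.91, Hedgehog and cilium genes at -0.54 and BMP and TGF-beta at -0.93. Lineage lists were neural stem cell regulators at -1.17 (NR2E1 at -3.68, VIM at -3.66), neuronal genes at -1.18, glial genes at -0.34 and pluripotency and neural crest genes at -0.55. Chromatin lists were Polycomb at -1.46 (BMI1 at -4.03), BAF at -1.43, COMPASS at -1.92, corepressors at -1.12, SAGA at -0.47 and DNA methylation at -1.92. Microcephaly genes lay at -0.88, autism risk genes at -2.0, sterol synthesis at -2.31 (percentile 2.82), apoptosis at -0.53, survival proteins at -1.16, adhesion at -2.37, Fanconi genes at -1.79, GPI anchor genes at -0.57, N-glycan and Golgi genes at -0.84 and the sort antigens at -3.11.

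Guides against core functions also lost ground in the library labelled CD24 over day 0. The mean abundance of core guides fell from 11.5 to 8.12 CPM, a summed ratio of 0.706, and olfactory receptor guides went from 13.5 to 13.9 CPM. The core median was -2.27 over 169 genes, of which 159 lay below 0 (79.7% of all genes did), under all 10000 random lists (central 95% from -1.30 to -0.68), and with counts under 3 set to 3 it was -4.09. It was -3.40 with a pseudocount of 0.2 CPM, -1.29 with 5 CPM, -1.03 without a guide filter and -0.50 with summed CPM, below every random list under each. The median of all genes was -0.96, and it was -0.22, -0.65, -0.89 and -0.42 with the olfactory receptor centre, no centring, median-of-ratios size factors and no guide filter.

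Below their random lists were 10 of the 43, where 2.15 random lists would be expected outside, both sides together. Ribosomal proteins had a median of -2.65 with all 43 measured genes below 0, and RPL6 had a value of -5.11. The proteasome lay at -3.12 over 21 genes (PSMA5 at -5.13, PSMA7 at -4.57), the spliceosome at -2.34 (PHF5A at -4.55) and mitosis at -2.15 (ANAPC10 at -4.79, ECT2 at -4.35). Complex I of the respiratory chain lay at -2.36 (TIMMDC1 at -4.36, NDUFB7 at -4.26). Cytosolic tRNA synthetases lay at -2.34, with the valine enzyme VARS at -4.40 past the rule. Anti-apoptotic proteins lay at -3.46 over 4 measured genes, none past the rule, with BCL2L1 at -4.27 and BCL2 at -3.70. EGF and FGF receptors and MAPK signalling lay at -2.34 over 12 genes, with NRAS at -4.14 and BRAF at -3.97. Integrin adhesion lay at -2.44 over 8 genes, with ITGA6 at -3.43 and FERMT2 at -3.32. The core union is the other. The adhesion call was lost under 8 of its 12 alternatives, the tRNA synthetase call under 5, and the EGF, FGF and MAPK, complex I and spliceosome calls under 3 each. Olfactory receptor genes lay above their random lists at -0.60 (percentile 99.96).

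The size rule was met by 2 genes upward and 89 downward. Without a guide filter 47 passed upward and 129 downward, and by summed CPM, chosen after seeing the data, the balance turned, with 172 upward and 118 downward. NRK, a kinase, had a median of 2.06 (2156 reads to 5344) and PCED1B of 1.80 (860 to 3430). The lowest were TFAP2B, a neural crest transcription factor (-5.65; 5759 reads to 310), STK32B (-5.32), the vesicle tether subunit VPS51 (-5.23; 5452 to 357), the ribosome assembly factors WDR74 (-5.16; 4673 to 0) and NOP58 (-5.14; 3654 to 2), SPOCK3 (-5.16), GFOD2 (-5.15), JMJD4 (-5.11; 4550 to 1), CCDC109B, a mitochondrial calcium uniporter subunit now named MCUB (-5.09; 4072 to 2), and DGAT1, which makes triglyceride (-5.04; 3900 to 1). For STK32B the measured guides fell to 0 reads, but a guide under the day-0 minimum went from 1 read to 1115. A measured SPOCK3 guide rose from 466 reads to 1176. Among list members past the rule were ORC6 of the origin recognition complex (-4.65), the growth factor receptor IGF1R (-4.66), the forebrain factor EMX2 (-4.70; 3367 to 2) and the mevalonate pathway enzyme PMVK (-4.18; 3086 to 0).

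Olfactory receptor genes also passed it, 3 of 251 (OR11H2 at -4.92, OR2J2 at -4.65 and OR2A7 at -4.42), against 2 of 169 core genes. Guides with few reads at day 0 could not count here either, since the 5th percentile of non-targeting guides was -4.05. Sets of olfactory receptor guides led to an expectation of 1.1 genes upward and 67.4 downward, and non-targeting sets to 8.05 and 5.46. Simulated unchanged libraries led to a mean of 4.75 upward and 14 downward, the latter with a range of 2 to 35. The count of 89 was above that range, but with a unit of 0.5 of the tallest peak, chosen after seeing the data, the mean was 151 and the range 86 to 216. With the guide range from olfactory receptor guides, chosen after seeing the data, it was 11, with 8 upward.

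Inside the random lists in this comparison were RNA polymerases at -1.53, DNA replication at -1.62 (percentile 6.18), the mitochondrial ribosome at -1.56 (percentile 3.44), G1/S drivers at -1.14 and G1/S brakes at -0.80. GPI anchor genes, which tether CD24 to the membrane, lay at -2.03 (percentile 2.71), with 19 of 20 below 0, as were 79.7% of all genes. By summed CPM over all 28 members, chosen after seeing the data, their ratio was 0.848 (percentile 17.65). N-glycan and Golgi genes lay at -0.68 and the sort antigens at -2.88. Growth lists were mTORC1 brakes at -0.93, PI3K-mTOR drivers at -1.12, Hippo brakes at -1.11, YAP/TEAD effectors at -2.20 and RAS brakes at -0.90. Notch lay at -0.78, Wnt at -0.27 (percentile 95.7), Hedgehog and cilium genes at -0.59 and BMP and TGF-beta at -0.96. Neural stem cell regulators lay at -1.36, neuronal genes at -0.87 (MAP2 at -3.74), glial genes at -0.45 and pluripotency and neural crest genes at -0.80. Polycomb lay at -0.62, BAF at -1.92, COMPASS at -1.45, corepressors at -1.44, SAGA at -2.11 and DNA methylation at 0.24 (percentile 97.1). Microcephaly genes lay at -1.10, autism risk genes at -1.23, sterol synthesis at -1.15, apoptosis at -1.11 and Fanconi genes at -1.07.

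**Figure D3:**
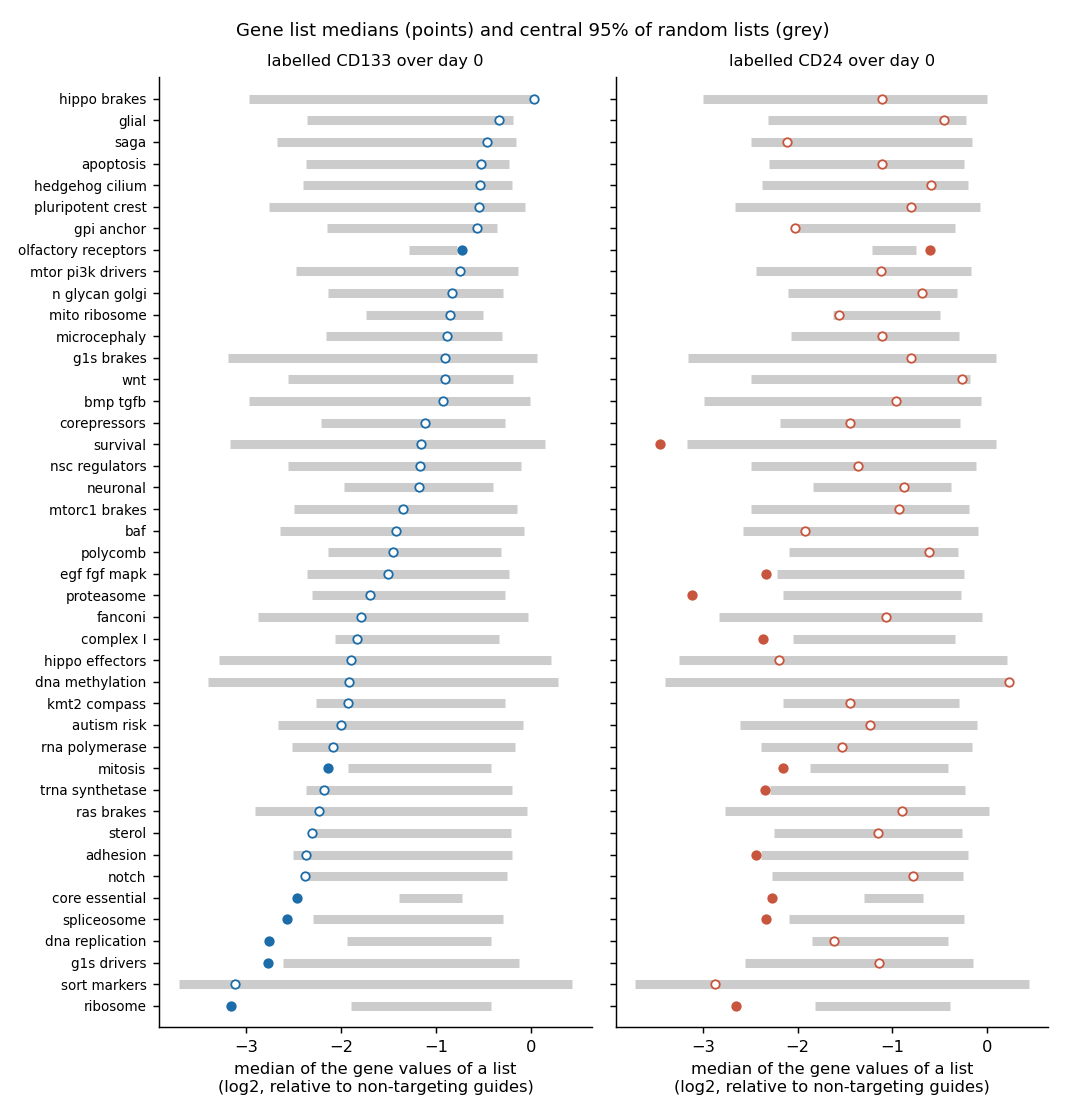
Median of the gene values of each of the 43 lists (points; horizontal axis, log2 relative to non-targeting guides) and the central 95% of 10000 random lists matched on day-0 abundance (grey), for the library labelled CD133 (left) and the library labelled CD24 (right) over day 0. Filled points lie outside the grey range; the core list lies at -2.46 and -2.27.

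The library labelled CD133 was then set against the library labelled CD24, the comparison that separates knockouts by cell state after differentiation. The medians could separate few lists here, since values pile up at 0: 43.3% of genes lay below 0 and 42.3% above, the core median was 0.00 and random lists of its size ran from -0.01 to 0.00. None of the 43 lists lay outside its random lists. By summed CPM, chosen after seeing the data, the core list (ratio 0.903, percentile 1.11), DNA replication (0.800, 2.29) and G1/S drivers (0.703, 2.06) were lower in the library labelled CD133, and N-glycan and Golgi genes were higher (1.31, 97.53). The last 3 lost their place with 1 gene left out, at percentiles 7.61 without ORC1, 9.32 without E2F1 and 89.9 without NANS. By percentile, the medians farthest out were SAGA at 0.49 (percentile 94.6), Hedgehog and cilium genes at 0.33 (93.9) and GPI anchor genes at 0.17 (92.0) above, and Fanconi genes at -0.22 (11.7), neuronal genes at -0.04 (14.6) and the spliceosome at -0.04 (14.6) below. The sort antigens, 2 genes, lay at -0.88 (17.6).

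Past the size rule were 22 genes higher and 24 lower in the library labelled CD133. Among the higher genes were CCDC109B (4.57; 3589 reads against 2), RLN3 (4.53), MAP6D1 (4.51), CPA6 (4.48), IMP4 of ribosome assembly (4.47), CBLN1 (4.44), PBX2 (4.39), DRAM1 (4.32) and USP29 (4.25; 2047 against 0). LATS2, a kinase of the Hippo cascade, had 2297 reads against 0 (4.20). The lower genes were led by ZNF718 (-5.41; 0 reads against 5550), GPATCH3 (-4.89), the lamin gene LMNB2 (-4.74; 1 against 2447), IHH (-4.73), CNNM1 (-4.73), UGT2B4 (-4.70), FASTKD3 (-4.66; 2 against 3403), CYP4A11 (-4.62), ITGB1BP2 (-4.55) and SLFN13 (-4.52). Several single guides went the other way, from -5.05 to 5.47 for RLN3. Sets of olfactory receptor guides led to an expectation of 34.9 genes higher and 20.02 lower, and sets of non-targeting guides to 5.34 and 1.58. Simulated unchanged libraries led to 15.1 (4 to 41) and 31.4 (11 to 69). Measured non-targeting guides had fewer zeros than targeting guides (6.48% against 28.6% in the library labelled CD133), so their sets are not a matched background. Both counts lay above the non-targeting expectation and inside these simulated ranges. They lay below the simulated ranges with a unit of 0.5 of the tallest peak, chosen after seeing the data, which were 43 to 89 higher and 26 to 84 lower.

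The changes from day 0 in the sorted libraries were compared gene by gene. Pearson's r across 12546 genes, which are not independent replicates, was 0.291, with a covariance of 0.676. Both changes share the day-0 library, and simulated unchanged libraries had an r of 0.203 (0.183 to 0.219) and a covariance of 0.338; the covariance exceeded the simulated one by 0.338. Sets of olfactory receptor guides had an r of 0.243 and a covariance of 0.381, and sets of non-targeting guides 0.260 and 0.166. With a unit of 0.5 of the tallest peak, chosen after seeing the data, the simulated r was 0.242 (0.229 to 0.253) and the covariance 0.16. Downward past the rule in both were 8 genes, against 0.47 from independent lists, 0.35 (0 to 1) in simulated libraries and 9 (5 to 13) in those with the smaller unit, and part of the excess may come from the shared day-0 library. The simulated lists were shorter than the observed ones with the first unit and longer with the smaller. Scaled to the observed lengths, chosen after seeing the data, the simulated counts were 4.92 and 2.86. The 8 genes were DAD1 of the oligosaccharyltransferase, the translation initiation factor EIF2S1, the kinetochore protein ZW10, NPM3, FBXO4, N4BP1, STK32B and TBC1D3F. STK32B and NPM3 fall under the naming rule, and the others were named after their values were seen. A STK32B guide under the day-0 minimum went from 1 read to 1115 in the library labelled CD24. TBC1D3F belongs to a family of near-identical copies, and its guides can cut several. No gene was past the rule in opposite directions.

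**Figure D4:**
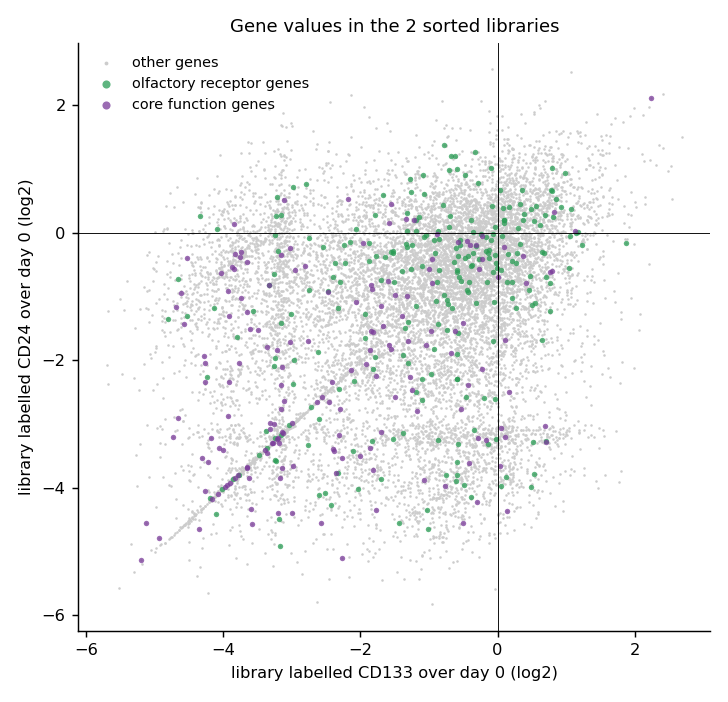
Median guide change of each gene in the library labelled CD133 (horizontal axis, log2) and the library labelled CD24 (vertical axis, log2) over day 0, with core function genes (purple) and olfactory receptor genes (green). The diagonal line at the lower left holds genes whose median guide has about 0 reads in both sorted libraries.

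In the authors' deposited table, which leaves out 249 of the 19114 genes and states no scale, the third column equals the difference of the others, and positive values mean higher in the second fraction named. Spearman's rho across genes between those values and the medians above was 0.745, 0.728 and 0.742 for the 3 comparisons, with the sign of the third deposited column turned to CD133 over CD24. Signs were the same for only 61.8%, 61.8% and 71.3% of genes. The deposited median of all genes was 0.21 in both comparisons with day 0, where the medians above were -1.0 and -0.96. PROM1 had deposited values of 0.36 and -0.003 over day 0, where its medians, which leave out the guide with 2202 reads, were -3.01 and -5.02. The authors' deposited table gave USP7 -6.68, BANP -6.76, NPM3 -6.75, PFDN2 -6.55 and POLR2J3 -6.52 as its lowest from day 0 to the library labelled CD133, and ENTPD7 7.59, EFNA4 7.26, ORC4 7.17, ASTE1 7.13 and RFX6 6.99 as its highest. From day 0 to the library labelled CD24, the authors' deposited table had ARMC7 at -7.07, ADCY4 at -6.63, JMJD4 at -6.60, ENO3 at -6.56 and TNFRSF10D at -6.54 at its low end and MS4A7 at 7.62, NKG7 at 7.25, ACAN at 7.18, CAPN3 at 7.12 and RNF32 at 7.07 at its high end. From the library labelled CD133 to that labelled CD24, the authors' deposited table ran from ENTPD7 at -6.95, KATNAL2 at -6.86, OR52K2 at -6.71, RD3L at -6.70 and HTR3C at -6.70 up to MBOAT4 at 7.78, ZNF718 at 7.18, ANKDD1A at 6.93, C2orf73 at 6.93 and ONECUT2 at 6.90. Of its 100 genes with the largest values, 69, 77 and 72 had under 3 guides at 2 CPM or more at day 0. ENTPD7, for one, had 0 reads at day 0, 2742 in the library labelled CD133 and 0 in the library labelled CD24.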

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

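The tests on the read peaks and on the sort antigens were chosen after the results were seen; the tests on GC content and abundance were fixed before. The test on the cost of a cut was fixed before its own result, but after an earlier test of that explanation had been run. Guides under the day-0 minimum took no part in the gene medians, yet some held signal above the 3 reads that a count of 0 allows. Of guides unread at day 0, 2485 had at least 157.5 reads in the library labelled CD133 and 177.5 in the library labelled CD24, which is 0.5 of the reads at the tallest peak. A left-out PROM1 guide had 2202 reads in the library labelled CD133.

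Reads per guide fell into separate peaks. If guides unread at day 0 had been lost from the culture, few would return; 15.1% of the 16431 did so in both day-10 libraries, which argues against loss as the whole cause (9.52% to 16.7% under other minimums). If few templates per guide were drawn into the sequencing, many would return in at least 1 library, and 48.5% did (37.7% to 50.6%). A small number of templates per guide is thus a candidate explanation for the unread guides and the extreme values of single guides. The day-0 and replated cells were separate parts of the culture. These shares therefore cannot tell few cells per guide in either part from few templates drawn into the PCR or sequencing. The reads of 1 template were not measured, and the smaller peaks leave open whether the tallest peak is that unit. No biological explanation was tested.

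Non-targeting guides rose against olfactory receptor guides between day 0 and day 10, 1.22-fold in the library labelled CD133 (95% bootstrap interval over guides 1.12 to 1.34) and 1.29-fold in the library labelled CD24 (1.19 to 1.41). Weighting to equal GC content left a ratio of at least 1.23 in both, against GC content as the cause. Weighting to equal abundance in the other sorted library brought the ratio to 1.08 (0.96 to 1.22) in the library labelled CD133. In the library labelled CD24 it was 1.13 (1.03 to 1.25), an interval that excludes 1 but not a ratio within 0.05 of it. The other sorted library shares any change since day 0. Weighting on it thus also favours olfactory receptor guides that rose, and it cannot decide. In 20 simulations of unchanged libraries, not part of the test fixed before, the ratio ran from 0.92 to 1.07 and from 0.94 to 1.07. These keep the abundance difference, so they argue against sampling at the tallest-peak unit as the whole cause. A cost of cutting DNA predicts that guides against other silent families (taste receptors, keratin-associated proteins, beta-defensins, vomeronasal receptors; 607 guides) also lose ground, and the lower ratio was 1.152 (1.03 to 1.29), in the predicted direction. That ratio was not weighted by abundance, and the earlier test had no outcome in favour, so a cost of cutting is a hypothesis.

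Between the sorted libraries, the summed reads of guides against the sort antigens ran against the sort labels, while the median difference of the PROM1 guides was 0. Exchanged labels would put GPI anchor guides, whose loss strips CD24, lower in the library labelled CD133. Their summed ratio was 1.26 (percentile 96.1, and 90.8 without GPAA1), the other way but inside the central 95% of random lists. An exchange thus stays open. With few templates alone, 0.21% of sets of 4 olfactory receptor guides reached a ratio as large as that of PROM1 in either direction, and 10.2% one as large as that of CD24. These shares neither exclude chance nor make it a full account, since the PROM1 ratio rests on 1 guide with 2202 of 2560 reads.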

How the results depend on the processing

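The guide range from olfactory receptor guides, the summed CPM of all guides and the zeros at 3 counts were chosen after seeing the data. No paired analysis was possible because each group has 1 library. No list or named gene called in 1 direction was called in the other under an alternative. Of 1548 alternatives for lists 107 crossed the middle of the random lists. Among these, adhesion in CD24 over day 0 went from percentile 2.22 to 80.4 without a guide filter, BAF from 9.94 to 98.1 there and, in CD133 over day 0 with summed CPM, from 28.2 to 98.2. The core list lay below its random lists over day 0 under all 12 alternatives in both sorted libraries. Of the alternatives for lists called over day 0, 190 kept the call and 26 lost it. Of those for lists not called, 1285 stayed so and 47 gained a call. The olfactory receptor centre and no centring shift all genes alike and cannot move a list among random lists, so the 2 calls gained and 1 lost under each come from the random draw. For named genes past the rule 535 kept their side and 41 lost it. Part of the 535 was fixed in advance, since those centrings move the guides and the non-targeting range alike. For the other named genes 1744 moved by less than the spread between guides, 160 by more and 8 passed the rule. The correlation across genes of the changes in both sorted libraries was 0.266 with zeros at 3 counts and 0.417 without a guide filter, and between these under the other alternatives run, of which the centrings, the 5 CPM filter, the mean and the thinning were added for it after seeing the data.

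The counts of genes past the size rule moved most, and the cause was not tested unless stated. In the order CD133 over day 0, CD24 over day 0 and CD133 over CD24, they were 2, 2 and 22 higher and 66, 89 and 24 lower. Simulated unchanged libraries under the same day-0 filter also passed fewer genes higher than lower over day 0. The balance of these counts over day 0 is thus no evidence of loss by itself. The olfactory receptor centre and no centring shift genes and the non-targeting range alike, so they hardly test these counts. A pseudocount of 5 CPM left 1, 1 and 10 higher and 28 and 10 lower in the first and last. Without a guide filter, which tests 19107 genes, 18, 47 and 44 were higher and 39 lower in the last. A filter of 5 CPM left 1 and 1 higher over day 0. Leaving out the most extreme guide, which also lowers the number of guides required, passed 32, 28 and 230 higher and 421, 534 and 151 lower. The central 95% of non-targeting guides as the range, stricter by construction, left 0, 0 and 0 higher and 4, 9 and 3 lower. A size threshold of 2 left 1 higher in CD24 over day 0. The range from olfactory receptor guides, wider on the low side, left 5, 8 and 1 higher and 8, 11 and 7 lower. Summed CPM passed 131, 172 and 71 higher and 149, 118 and 133 lower, more higher than lower in CD24 over day 0, with 95.5 genes per direction from the olfactory receptor sets alone.

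The number of lists called higher in CD133 over day 0, 1 in the main setting, was 2 with unmatched lists, a pseudocount of 0.2 CPM, no guide filter or zeros at 3 counts, 0 with a filter of 5 CPM and 4 with summed CPM. In CD24 over day 0 it was 2 with unmatched lists, no guide filter or summed CPM. In CD133 over CD24, where none was called, summed CPM called 3 lower and 1 higher. The core list was among them, with a log2 ratio of -0.147. Simulated libraries with a unit of 0.5 of the tallest peak passed 15.2, 20.9 and 66.1 genes higher and 143, 151 and 53.9 lower, against 3.8, 4.75 and 15.1 and 27.5, 14 and 31.4. The number of templates behind a guide was not measured, and thinning reads to the shallowest library does not test it.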

Other observations

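All tests in this part were chosen after the results were seen. Summing the CPM of all guides of a list, including those unread at day 0, brought out some groups that the medians did not. Hedgehog and cilium genes were 1.71-fold higher in the library labelled CD133 than at day 0 (percentile 99.99 of random lists); without SUFU, which restrains Hedgehog signalling, the ratio was 1.37 (percentile 97.9). In the library labelled CD24 they were 1.35-fold higher (percentile 97.8), and without SUFU 1.22-fold (90.3), so the second rests on SUFU. SUFU itself went from 15.7 to 372 CPM, and to 149 CPM in the library labelled CD24. In the library labelled CD133, the BAF list was 1.33-fold higher, and without ARID2 1.23-fold (percentile 92.2).

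Lower by summed CPM in the library labelled CD133 were RNA polymerases (ratio 0.465) and the proteasome (0.640), which the medians had left inside the random lists, and tRNA synthetases (0.710), which kept no such place without VARS (percentile 3.76). In the library labelled CD24 the same held for RNA polymerases (0.542), DNA replication (0.755), still at percentile 0.34 without ORC6, sterol synthesis (0.623), which kept its place without PMVK (0.664, percentile 1.78), and the Fanconi list (0.720), which did not without FANCA (percentile 5.02), nor did the mitochondrial ribosome (0.888) without MRPL37 (3.52). Between the sorted libraries, core genes had a ratio of 0.903 (percentile 1.11), still 0.914 (2.38) without CARS.

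The core gene DBF4, the activating subunit of the kinase that fires replication origins, had values of 2.23 and 2.11 over day 0 in the libraries labelled CD133 and CD24 but was not past the size rule, and was named after its values were seen. Its guides disagreed: of 3 measured, 2 lay above the non-targeting range and 1 below it in both, from -4.79 to 2.24 and from -4.81 to 2.76, and its total went from 1331 reads to 2089 and 2135.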
